A study of Mus musculus with 18 samples.

How the data were processed

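Expression was measured with Illumina MouseWG-6 bead arrays, on which each probe is read out from many beads of 1 array. Total RNA came from cultured skeletal muscle myoblasts of mice with loxP-flanked Gata4. Per the labels, the cells had been infected with an adenovirus carrying nuclear beta-galactosidase (Wt) or Cre recombinase (KO), or with a retrovirus carrying GATA4 (OE), and were collected in growth medium (day 0) or after 3 days in differentiation medium (day 3). The 18 arrays form 6 labelled groups of 3. The kind of virus differs between Wt and OE as well as its cargo. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these samples only, which may be technical.

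Per the file headers, the authors deposited a non-normalised table with a mean bead intensity and a detection p-value for each of 45281 probes on each array. The intensities were on a linear scale with no background subtracted. The detection p-values moved in steps that correspond to 936 negative control probes. A further table deposited by the authors held processed intensities of the same arrays on a linear scale. Its column medians lay between 105.1 and 110.7, its normalisation is not given in the sources used here, and each column had a rank correlation of 1 with the non-normalised column of the same title and of at most 0.85 with any other. The mapping of columns to titles is therefore the same in both tables. No pair of arrays held identical values. The scanner software is not given in the sources used here.

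Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, with background parameters inferred from the detection p-values, an offset of 16 and quantile normalisation between arrays (the neqc method), giving log2 intensities. Probes with a detection p-value below 0.05 on at least 3 arrays were kept, which left 22365. Gene names came from the platform annotation, updated through Entrez identifiers against the mouse RefSeq gene table of assembly GRCm38.p6. Of all probes, 34885 had 1 symbol, 18 had several and 10378 had none. An identifier match was found for 34807 of the first kind. Of the kept probes, 19031 had 1 symbol, and the probe with the highest mean represented each of 11921 genes. Probes with several symbols or none were left out of the gene tests.

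A linear model with 1 mean per labelled group was fitted to all 18 arrays with limma (12 residual degrees of freedom), with moderated statistics and Benjamini-Hochberg adjustment over the genes of each of 9 comparisons. These were KO against Wt and OE against Wt at each day, day 3 against day 0 within each label, and the differences of the KO and OE changes over time from the Wt change. Genes with an adjusted p below 0.05 count as past the threshold. For 25 gene lists fixed before the data were examined, camera tested the 22 with at least 5 measured members, with a preset correlation between genes of 0.01, adjustment over lists within a comparison, and a repeat with an estimated correlation. Genes named in the text were to be Gata4, the strongest genes past the threshold of each comparison, and members of the lists. Since no gene passed the threshold, the list members named below are the up to 4 with the largest absolute difference in a list with a camera adjusted p below 0.05, or members described array by array or by their range, and each was not past the threshold over all genes. Aoc3 is an exception, chosen after its values were seen because it was the single member of its list below 0.05 when adjusted over the list alone.

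The gene test was tested on simulated data for KO against Wt at day 0, with 11921 genes, the measured gene means and the spread of the fit. With no change added, 0 genes passed. Of 50 genes changed by a log2 of 1, 40% were recovered, and of 50 changed by a log2 of 2, 84%. The changed genes were picked at random, and noise was drawn independently for each gene and array. These shares therefore leave out differences between arrays that many genes share, and do not hold for genes with a large spread. Mx2, for example, had a measured difference of 3.11 ± 1.42 (SE) in this comparison and was not past the threshold. Alternatives comprised other background corrections and normalisations, the authors' processed values, other detection filters, other ways of choosing probes, array weights, the replicate number as a block, a fit to the compared groups alone, a minimum log2 difference of 1, and leaving out each array. The number of arrays limits the precision of every value below. Slide positions were not used here.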

Results

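Expression in mouse skeletal muscle myoblasts was compared between cells labelled Wt, KO and OE for the transcription factor GATA4, in growth medium and after 3 days in differentiation medium, with 3 arrays per group. The arrays were alike in technical level. Between 16974 and 19966 of 45281 probes were detected per array, and the median signal lay between 96.59 and 110.4 intensity units against a background of 90.73 to 103.3.

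Gata4, the targeted gene, was represented by 1 probe, ILMN_2817903, which was close to background on every array. Its signal ranged from 91.91 to 116.3 intensity units, and it was detected on 5 of 18 arrays. On the log2 scale its mean was 5.02 ± 0.33 (SD, n = 3) in the day 0 group labelled Wt, 4.48 ± 0.37 in KO and 4.56 ± 0.21 in OE. At day 3 it was 4.67 ± 0.49 in Wt, 4.5 ± 0.13 in KO and 4.41 ± 0.06 in OE. The lowest value of any probe was 4.13. The KO arrays differed from Wt by -0.53 ± 0.25 (SE) at day 0 and by -0.17 ± 0.25 at day 3, with limma adjusted p of 0.78 and 0.94. The OE arrays differed by -0.45 ± 0.25 and -0.26 ± 0.25, with adjusted p of 0.97 and 0.92. The position of the probe relative to the deleted exons and to the viral sequence was not analysed here. At this signal the probe does not check the labels, and groups are called by their labels throughout.

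**Figure D1:**
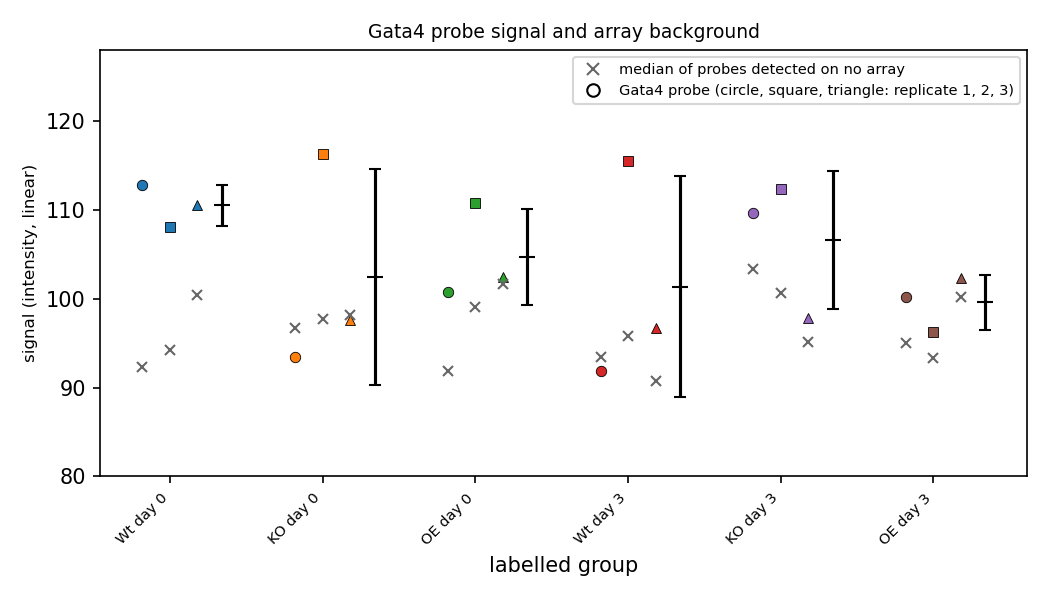
Signal of the Gata4 probe on each array (linear intensity, vertical axis not starting at 0) by labelled group, with the mean and SD of 3 arrays beside each group and the array background as crosses. All 18 signals lie between 91.91 and 116.3, beside backgrounds of 90.73 to 103.3.

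Over 11921 genes, the median correlation was 0.941 for the 18 pairs of arrays within labelled groups and 0.9378 for the 135 pairs between groups. The KO day 3 arrays had correlations of 0.9842 to 0.9949 with each other. The closest array had the same label for 7 of 18 arrays, and for 0 arrays did both of the 2 closest. Each of the 18 arrays belonged to a set of 3 that were mutually closest, with correlations of 0.9849 to 0.9949 within these 6 sets. All 6 sets held more than 1 label and 5 held both days. Of the 18 pairs within sets, 4 shared a labelled group, where 2.12 would be met by chance (permutation test of the labels, one-sided, 100000 draws, p = 0.15). The sets were the same for all 18 arrays when computed on the authors' processed values.

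**Figure D2:**
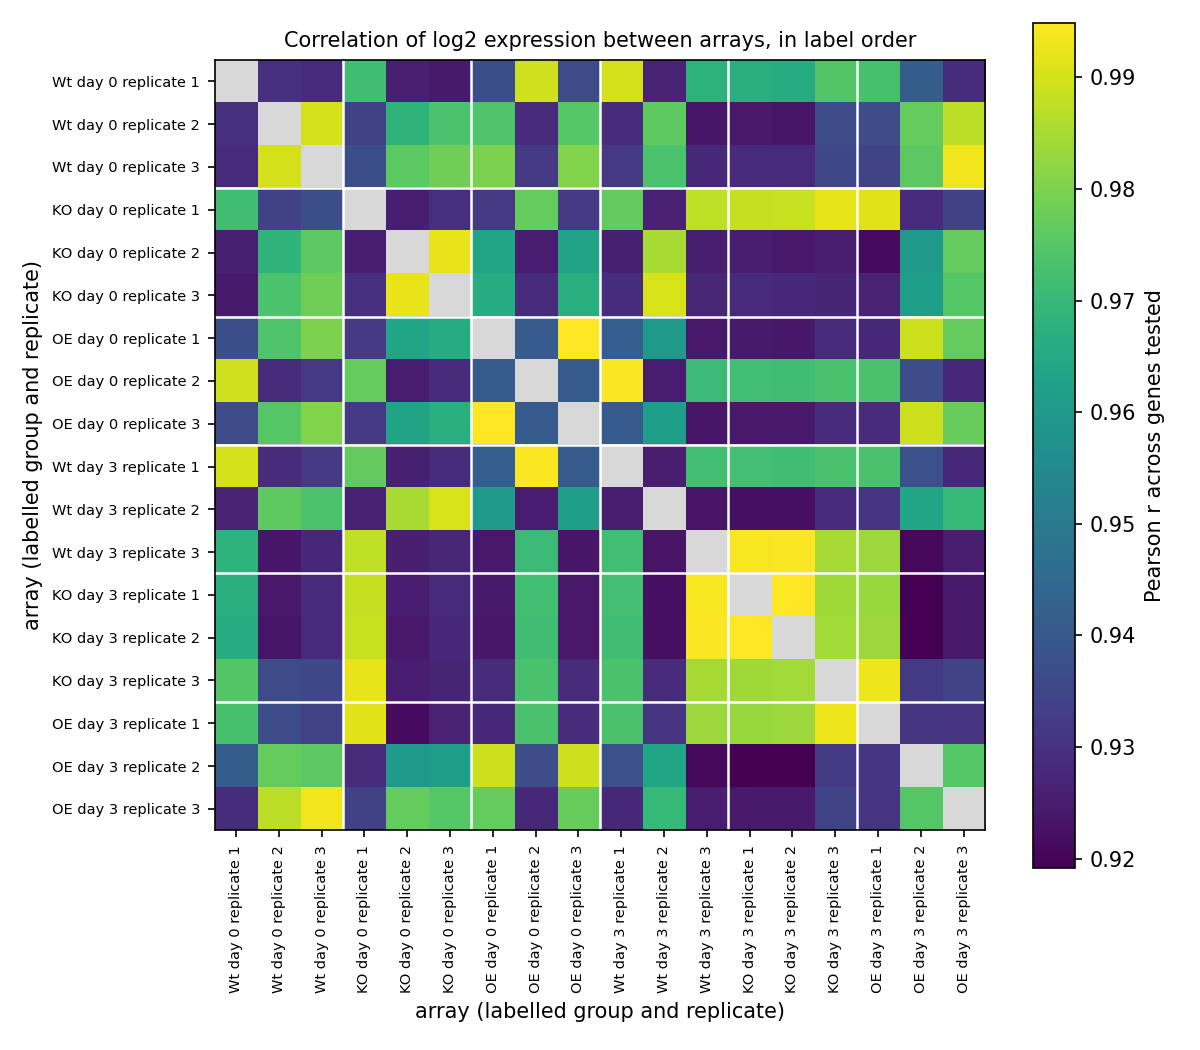
Pearson correlation of log2 expression over 11921 genes between all pairs of the 18 arrays, in the order of their labels, with white lines between labelled groups. The brightest cells lie both inside and outside the labelled blocks, and the 18 pairs within labelled groups have a median of 0.941.

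Muscle genes and cell cycle genes parted the arrays in opposite directions within every labelled group except KO day 3, whose sarcomere means were 11.36, 11.38 and 11.11 and whose cell cycle means were 7.08, 7.06 and 6.72. Ckm, the muscle creatine kinase, lay between 10.87 and 11.39 on 9 arrays and between 6.78 and 8.05 on the other 9. The same 9 arrays had Top2a, the DNA topoisomerase of dividing cells, between 5.13 and 5.75, against 7.82 to 8.82 on the others. At day 0, Wt replicate 1, KO replicate 1 and OE replicate 2 had Ckm values of 11.11, 11.25 and 11.21. At day 3, Wt replicate 2, OE replicate 2 and OE replicate 3 had Ckm values of 7.87, 6.89 and 7.4. Usp18, an interferon-induced protease, was at 12.41 and 12.4 in KO day 0 replicates 2 and 3 and at 12.52 in Wt day 3 replicate 2. It was at 9.94, 9.72 and 9.77 in Wt day 0 replicate 1, OE day 0 replicate 2 and Wt day 3 replicate 1, and at most 5.43 on the other 12 arrays.

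**Figure D3:**
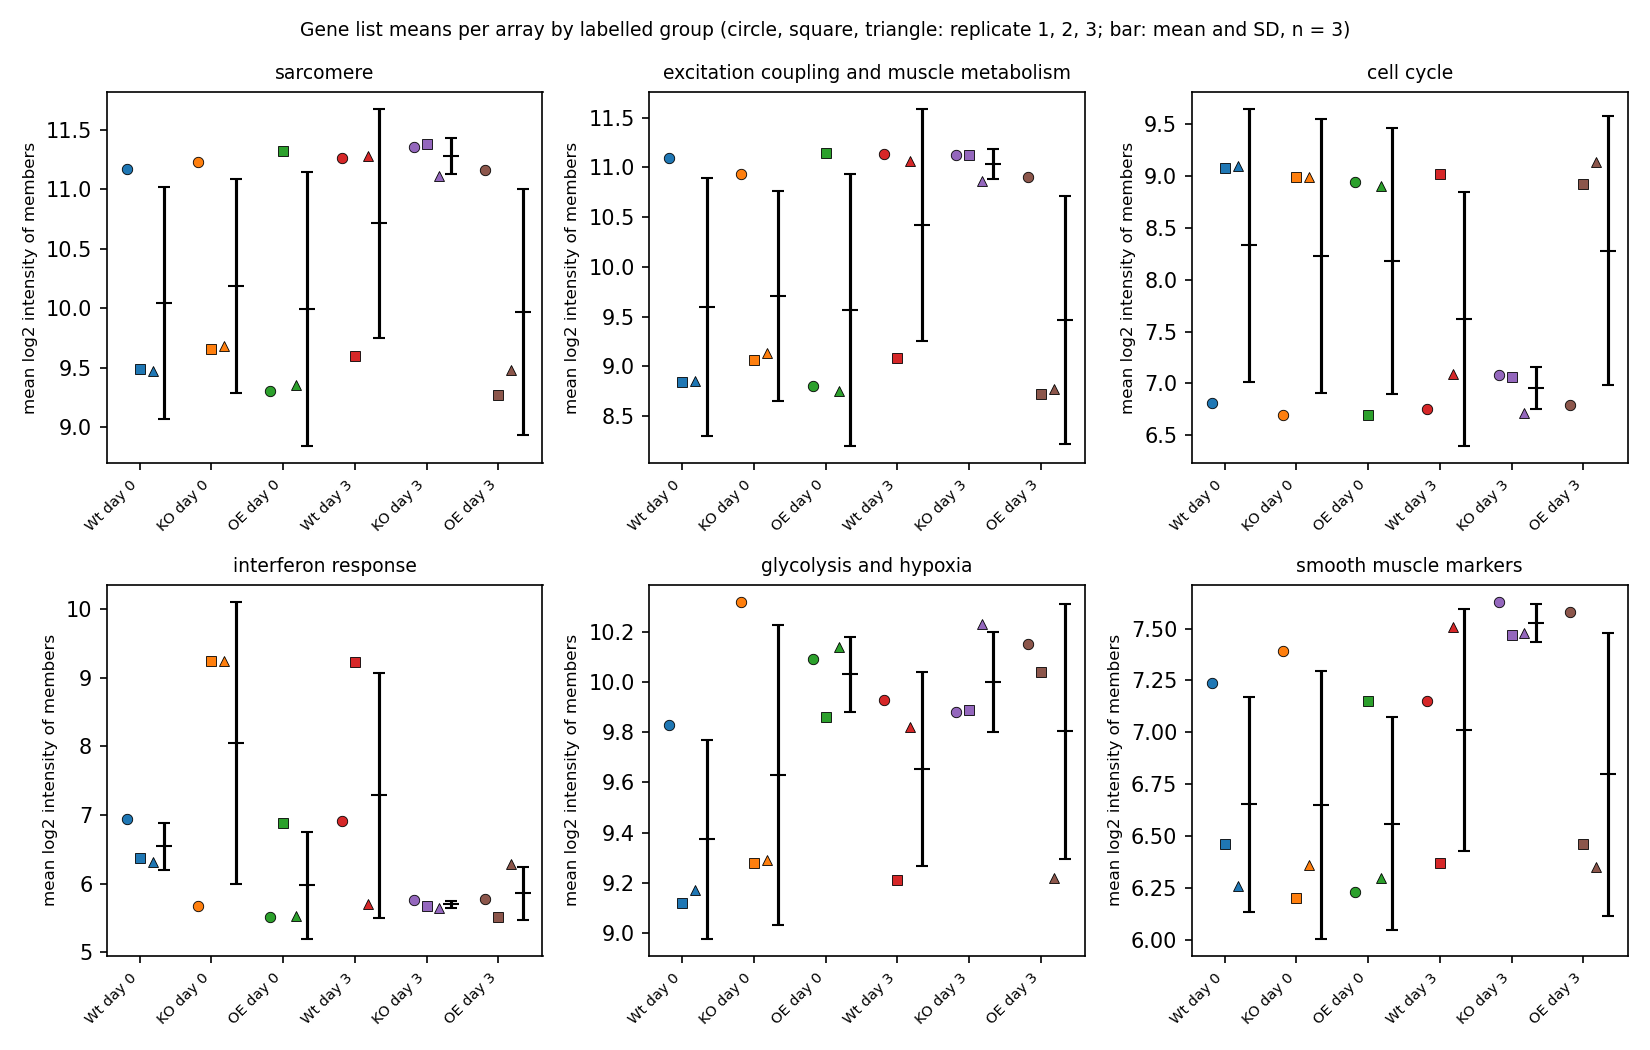
Mean log2 intensity of 6 gene lists on each array by labelled group, with symbols for replicates 1 to 3 and the mean and SD of 3 arrays. In the sarcomere list the arrays span 9.27 to 11.38, and every labelled group except KO day 3 holds arrays near both ends.

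The first comparison, KO against Wt at day 0, asks what Cre recombinase changed in myoblasts labelled as in growth medium. Interferon-induced genes had the largest difference of any list, with all 31 measured members higher in the KO group and a median log2 difference of 1.51. Mx2, an antiviral GTPase, was at 8.32 ± 3.23 (SD, n = 3) in KO and 5.21 ± 1.58 in Wt, and Bst2, a membrane tether of viruses, at 9.67 ± 2.67 and 6.82 ± 1.07. NF-kB and inflammatory genes were higher for 23 of 26 members, with a median of 0.4. Icam1, an adhesion molecule, was at 7.47 ± 0.89 in KO and 5.39 ± 0.3 in Wt, while the chemokine Cxcl12 was at 8.48 ± 1.67 and 10.57 ± 0.69. Of the p53 targets, 20 of 26 were higher, with a median of 0.24. Pmaip1, which encodes the apoptosis protein Noxa, was at 8.55 ± 0.31 against 7.44 ± 0.1 and was the single member with p below 0.05 adjusted over the list alone (0.028). Of 13 cholesterol synthesis genes 10 were lower, with a median of -0.25, and Fdps was at 9.04 ± 0.88 in KO and 10.19 ± 0.8 in Wt. Camera gave adjusted p of 1.4e-13 for the interferon list, 0.00022 for NF-kB, 0.0044 for p53 and 0.047 for cholesterol synthesis. With an estimated correlation the adjusted p were 0.53, 0.2, 0.53 and 0.76. The interferon list mean was 9.24 in KO replicates 2 and 3 and 5.67 in KO replicate 1, so the difference was carried by 2 of 3 arrays. The interferon median was 2.51 without KO day 0 replicate 1, 0.92 without replicate 2 and 0.85 without replicate 3, each with its call kept. The p53 call was lost without Wt day 0 replicate 1 (median 0.2) or KO day 0 replicate 2 (0.28), and its median was 0.41 without Wt day 0 replicate 2 and 0.44 without KO day 0 replicate 1. The cholesterol call was lost without Wt day 0 replicate 1 (-0.1), KO day 0 replicate 1 (-0.42) or KO day 0 replicate 2 (-0.26), and without Wt day 3 replicate 3, OE day 3 replicate 2 or OE day 3 replicate 3 (-0.25 each), and its median was -0.38 without KO day 0 replicate 3. It was also lost with normexp by signal (median -0.13), no background correction (-0.1), the authors' values (-0.09), the stricter detection filter (-0.21) and array weights (-0.19). No gene was past the threshold in limma, and 763 had an unadjusted p below 0.05, where 596 are met by chance. Without KO day 0 replicate 1 the count past the threshold was 10, and with array weights it was 1055. Array weights favour arrays near their group, so p-values under them, here and below, may be too small.

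KO against Wt at day 3 asks the same after differentiation. Contractile and metabolic muscle genes had higher means in the KO group, with 29 of 33 sarcomere genes and 25 of 25 genes of excitation coupling and muscle metabolism higher, at medians of 0.58 and 0.56. Myoz1, a Z-disc protein, was at 8.61 ± 0.5 (SD, n = 3) in KO and 7.01 ± 2.32 in Wt, and Ckmt2, the mitochondrial creatine kinase, at 11.48 ± 0.05 and 9.98 ± 1.62. Myogenic regulators had a median of 0.38, with Cdkn1c at 13.12 ± 0.58 and 11.8 ± 1.38. Of 31 cell cycle genes 29 were lower, with a median of -0.73, and Cenpa, a centromere histone, was at 9.05 ± 0.29 against 10.44 ± 1.54. All 31 interferon genes were lower, with a median of -1.41, and Isg15 was at 6.67 ± 0.19 against 10.16 ± 3.15. Glycolysis and hypoxia genes had a median of 0.37, oxidative phosphorylation genes of 0.17 and smooth muscle markers of 0.59. Aoc3 was the single smooth muscle marker below 0.05 adjusted over the list alone (0.026), at 5.01 ± 0.2 against 4.42 ± 0.17, and was detected on 3 of 3 KO arrays and 0 of 3 Wt arrays. Both means lay near the lowest value of any probe, 4.13, and its limma adjusted p over all genes was 0.94. Camera gave these 8 lists adjusted p between 2.3e-13 and 0.0084. With an estimated correlation the adjusted p was 0.66 for each. The spread lay in the Wt group, where replicate 2 had a sarcomere mean of 9.6 beside 11.26 and 11.28. Without Wt day 3 replicate 2 the medians were 0 for sarcomere, -0.05 for excitation coupling, -0.06 for myogenic regulators, 0.07 for cell cycle, 0.07 for glycolysis, 0.02 for oxidative phosphorylation and 0.13 for smooth muscle. Each of these calls was then lost, and that of the cell cycle list was also lost without KO day 3 replicate 3, at a median of -0.66. The interferon call was kept at -0.52 without Wt day 3 replicate 2, where the list mean was 9.23 beside 6.92 and 5.71, and at -2.18 without Wt day 3 replicate 3. Medians without Wt day 3 replicate 1 were 0.92 for sarcomere, 0.9 for excitation coupling, 0.62 for myogenic regulators and -1.23 for cell cycle. Those without Wt day 3 replicate 3 were 0.9 for excitation coupling and 0.26 for oxidative phosphorylation. Array weights ended 6 of the calls, at medians of 0.25 for sarcomere, 0.21 for excitation coupling, 0.1 for myogenic regulators, -0.17 for cell cycle, 0.18 for glycolysis and 0.1 for oxidative phosphorylation. No gene was past the threshold in limma, and 273 had an unadjusted p below 0.05, fewer than the 596 met by chance.

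OE against Wt at day 0 compares retroviral GATA4 with adenoviral beta-galactosidase in cells labelled as in growth medium. It cannot part GATA4 from the kind of virus. Cell cycle means were 6.7 in OE replicate 2 and 6.81 in Wt replicate 1, against 8.9 to 9.1 on the other arrays compared. Genes of glycolysis and hypoxia were higher for 16 of 18 members, with a median log2 difference of 0.54. Car9, a hypoxia-induced carbonic anhydrase, was at 8.43 ± 1.01 (SD, n = 3) in OE and 5.12 ± 1.28 in Wt. Slc2a1, the glucose transporter GLUT1, was at 11.02 ± 0.48 and 10.03 ± 0.38, and Ndrg1 at 7.69 ± 0.79 and 6.29 ± 0.44. Car9 was at 9, 7.26 and 9.02 on the OE arrays and at 6.59, 4.48 and 4.28 on the Wt arrays. The list mean was 10.09, 9.86 and 10.14 on the OE arrays and 9.83, 9.12 and 9.17 on the Wt arrays. OE replicate 2 and Wt replicate 1, which had nearly equal means, belong to 1 mutually closest set. Their sarcomere means were 11.32 and 11.17, against 9.3 to 9.49 on the other arrays compared. The highest glycolysis mean of all 18 arrays was 10.32, in KO day 0 replicate 1. Markers of fibroblasts and mesenchymal progenitors were higher for 7 of 11 members and lower for 4, with a median of 0.33. Cd34, a surface protein of progenitor cells, was at 7.53 ± 0.07 in OE and 5.94 ± 0.82 in Wt, and Thy1 at 8.47 ± 1.53 and 6.61 ± 0.47. Camera gave the glycolysis list an adjusted p of 1.8e-06 and the fibroblast list 0.0498, and with an estimated correlation the adjusted p were 0.34 and 0.17. The fibroblast call was lost without Wt day 0 replicate 3 (median 0.45), OE day 0 replicate 1 (0.42), KO day 0 replicate 2 or KO day 0 replicate 3 (0.33 each), and its median was 0.16 without OE day 0 replicate 2. It was also lost with cyclic loess (0.26), median scaling (0.39), no detection filter (0.13) and the replicate block. No gene was past the threshold in limma, and 612 had an unadjusted p below 0.05, where 596 are met by chance. With array weights 961 genes were past the threshold.

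OE against Wt at day 3 gave lower means for muscle genes in the OE group. Of 33 sarcomere genes 32 were lower, with a median of -0.7, as were all 25 genes of excitation coupling and muscle metabolism, with a median of -0.93, and 22 of 24 myogenic regulators, with a median of -0.62. Pvalb, the calcium buffer parvalbumin, was at 7.1 ± 2.47 (SD, n = 3) in OE and 9.5 ± 2.34 in Wt, and Tcap, the titin cap protein, at 9.59 ± 1.35 and 10.94 ± 1.7. Mymk, the myoblast fusion protein myomaker, was at 9.49 ± 1.28 and 10.65 ± 0.94. Oxidative phosphorylation genes had a median of -0.17. All 31 cell cycle genes were higher, with a median of 0.66, and Bub1b was at 8.13 ± 1.9 against 6.91 ± 1.73. All 31 interferon genes were lower, with a median of -1.23. Of 15 genes of satellite cell and myoblast identity 11 were higher, with a median of 0.32, and Megf10 was the single member below 0.05 adjusted over the list alone (0.045), at 10.78 ± 0.14 against 10.28 ± 0.17. Camera gave the 7 lists adjusted p between 1.9e-11 and 0.0054, while with an estimated correlation the adjusted p was 0.16 for the identity list and 0.8 for the other 6. Without Wt day 3 replicate 2 the interferon median was -0.33 and the identity median 0.31, and both calls were lost. Without OE day 3 replicate 2 the calls of the identity list (0.16), oxidative phosphorylation (-0.08) and cell cycle (0.34) were lost. Without Wt day 3 replicate 3 those of myogenic regulators (-0.34), oxidative phosphorylation (-0.06) and cell cycle (0.39) were lost. The cell cycle call was also lost without Wt day 3 replicate 1 or OE day 3 replicate 3, at 0.27 each. Other calls were kept at medians that moved with single arrays. Without Wt day 3 replicate 2 or OE day 3 replicate 1 the medians were -1.28 and -1.4 for sarcomere, -1.52 and -1.58 for excitation coupling, -1.09 and -0.99 for myogenic regulators, 1.45 and 1.46 for cell cycle and -0.27 in both cases for oxidative phosphorylation. Without OE day 3 replicate 1 the identity median was 0.53. The sarcomere median was -0.44, -0.42 and -0.4 without Wt day 3 replicate 1, Wt day 3 replicate 3 and OE day 3 replicate 2, and that of excitation coupling -0.57, -0.57 and -0.53. The myogenic median was -0.38 without Wt day 3 replicate 1, -0.37 without OE day 3 replicate 2 and -0.36 without OE day 3 replicate 3, which also gave a sarcomere median of -0.41. Oxidative phosphorylation had -0.1 without Wt day 3 replicate 1, and interferon genes -1.86 without Wt day 3 replicate 3. The arrays of both groups parted, with sarcomere means of 11.16, 9.27 and 9.48 in OE and 11.26, 9.6 and 11.28 in Wt. The high levels of both groups were thus close, as were the low ones. The lower muscle means in OE came with fewer arrays at the high level. Leaving out 1 array never evened these shares, so calls kept that way do not show a lower level on each OE array. No gene was past the threshold in limma, and 471 had an unadjusted p below 0.05, fewer than the 596 met by chance.

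Day 3 against day 0 in the arrays labelled Wt asks what differentiation changed in control cells. Muscle genes had higher means at day 3, with 32 of 33 sarcomere genes, 25 of 25 excitation coupling genes and 22 of 24 myogenic regulators higher, at medians of 0.65, 0.7 and 0.5. Ckm was at 10.07 ± 1.91 (SD, n = 3) at day 3 and 8.54 ± 2.23 at day 0, and Myh4, a fast myosin heavy chain, at 6.72 ± 1.85 and 4.99 ± 1.15. Of 31 cell cycle genes 30 were lower, with a median of -0.71, and Cdk1 was at 8.78 ± 1.54 against 10.02 ± 1.67. Interferon genes were higher for 27 of 31 members, with a median of 0.68. Camera gave the 5 lists adjusted p between 0.00014 and 0.0035, and with an estimated correlation the adjusted p was 0.8 for each. Without Wt day 3 replicate 2 the interferon median was -0.12 and its call was lost, as it was with array weights, at 0.32. The sarcomere call was lost without Wt day 0 replicate 3 or Wt day 3 replicate 1, at a median of 0.37 in both cases. The calls of myogenic regulators, excitation coupling and cell cycle were each lost without any 1 of Wt day 0 replicates 2 and 3 and Wt day 3 replicates 1 and 3. The medians were then 0.27 to 0.34, 0.37 to 0.41 and -0.46 to -0.32. Without Wt day 0 replicate 1 or Wt day 3 replicate 2 the calls were kept at larger medians, 1.2 and 1.21 for sarcomere, 1.4 and 1.36 for excitation coupling, 1.06 and 0.93 for myogenic regulators and -1.41 and -1.48 for cell cycle. The sarcomere median was 0.42 without Wt day 0 replicate 2 and 0.36 without Wt day 3 replicate 3, and the interferon median 1.4 without the latter. The spread within each day was larger than the difference between days, as replicate 1 of day 0 had a sarcomere mean of 11.17 and replicate 2 of day 3 a mean of 9.6. No gene was past the threshold in limma, and 476 had an unadjusted p below 0.05, fewer than the 596 met by chance. With array weights 663 genes were past the threshold.

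Day 3 against day 0 in the arrays labelled KO gave the largest count of small p-values, with 992 genes at an unadjusted p below 0.05. By chance 596 are met, and no gene was past the threshold in limma. With array weights 6266 genes were past it. Of 33 sarcomere genes 31 were higher at day 3, with a median of 1.24, as were all 25 excitation coupling genes, with a median of 1.26, and 23 of 24 myogenic regulators, with a median of 0.89. Fhl1, a muscle LIM protein, was at 13.08 ± 0.02 (SD, n = 3) at day 3 and 11.26 ± 1.46 at day 0. Ampd1, the muscle AMP deaminase, was at 10.4 ± 0.2 and 8.01 ± 1.8. All 9 smooth muscle markers were higher, with a median of 0.86, and Aoc3, detected on 3 of 3 day 3 arrays and 0 of 3 day 0 arrays, was below 0.05 adjusted over the list alone (0.022). Aoc3 was near background here too, with a limma adjusted p of 0.49 over all genes. Glycolysis and oxidative phosphorylation genes had medians of 0.46 and 0.29. Of 31 cell cycle genes 30 were lower, with a median of -1.43, and Aurkb, a mitotic kinase, was at 5.53 ± 0.14 against 7.55 ± 1.7. All 31 interferon genes were lower, with a median of -2.23, and 21 of them were below 0.05 adjusted over the list alone. Oasl2 was at 4.69 ± 0.25 and 8.81 ± 3.71. NF-kB genes had a median of -0.9, with the chemokine Ccl2 at 6.55 ± 0.64 and 8.61 ± 0.77, and p53 targets a median of -0.59. Camera gave the 10 lists adjusted p between 2.6e-16 and 0.012. With an estimated correlation the adjusted p lay between 0.29 and 0.5. The glycolysis call was lost without KO day 0 replicate 2, KO day 0 replicate 3 or KO day 3 replicate 3, at medians of 0.28, 0.35 and 0.38, and in a fit to the compared groups alone, at 0.46 with an adjusted p of 0.055. Without KO day 0 replicate 1 the medians were -2.26 for cell cycle, 0.85 for glycolysis and 1.3 for smooth muscle markers, and without KO day 0 replicate 3 that of oxidative phosphorylation was 0.19. The day 3 arrays were alike, with sarcomere means of 11.36, 11.38 and 11.11, while KO day 0 replicate 1 stood at 11.23 beside 9.66 and 9.68. The groups did not overlap for 2048 genes, or 17.2%, where chance gives 10%, and for 5.55% to 11% of genes in the other 6 comparisons of 2 groups.

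Day 3 against day 0 in the arrays labelled OE gave no list past the threshold of camera and no gene past that of limma. An unadjusted p below 0.05 was found for 545 genes, where 596 are met by chance. The sarcomere mean was 9.3, 11.32 and 9.35 on the day 0 arrays and 11.16, 9.27 and 9.48 on the day 3 arrays. Without OE day 0 replicate 2, 5 lists were past the threshold, 4 higher at day 3 and 1 lower. Without OE day 3 replicate 1, 5 lists were past it, 1 higher and 4 lower.

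The change over time was then compared between labels. For KO against Wt, all 31 interferon genes had a lower change, with a median log2 difference of -2.74, and Usp18 had a difference of -6.92 ± 3.04 (SE). NF-kB genes and p53 targets had medians of -0.6 and -0.38, and oxidative phosphorylation genes of 0.22. The camera adjusted p were 4.6e-29, 1.4e-05, 0.0023 and 0.039, and with an estimated correlation the adjusted p were 0.23, 0.092, 0.6 and 0.82. Without Wt day 3 replicate 2 the p53 median was -0.12 and that of oxidative phosphorylation 0, and both calls were lost. The latter was also lost without Wt day 0 replicate 1 (0.08), KO day 0 replicates 2 (0.17) or 3 (0.11), or KO day 3 replicates 1 (0.15) or 2 (0.16), and its median was 0.35 without KO day 0 replicate 1 and 0.36 without Wt day 3 replicate 3. It was also lost with cyclic loess (0.17), no detection filter (0.2), the mean of probes (0.18), array weights (0.12) and the fit to the compared groups (0.22). The interferon and NF-kB calls were kept without Wt day 3 replicate 2, at medians of -1.81 and -0.32. The p53 median was -0.66 without KO day 0 replicate 1 and -0.6 without KO day 3 replicate 3. For OE against Wt, genes of excitation coupling had a median of -0.97, interferon genes of -0.87, myogenic regulators of -0.61, sarcomere genes of -0.58 and glycolysis genes of -0.43. Pvalb had a difference of -2.84 ± 2.49, which was -4.77 without Wt day 0 replicate 1 and -1.17 without OE day 0 replicate 2. Car9 had a difference of -2.52 ± 1.47, which was -3.45 without OE day 3 replicate 2 and -1.57 without OE day 3 replicate 3. The camera adjusted p lay between 0.0089 and 0.043, and the adjusted p with an estimated correlation was 0.81 for all 5. Without OE day 0 replicate 2 the medians were 0.07 for sarcomere, -0.01 for myogenic regulators and -0.17 for excitation coupling, and without Wt day 3 replicate 2 the interferon median was -0.01, each with its call lost. All 5 calls were lost without some other arrays too. Those of the 3 muscle lists were lost without any 1 of Wt day 0 replicates 2 and 3, OE day 0 replicate 2, Wt day 3 replicates 1 and 3 and OE day 3 replicates 2 and 3, and that of myogenic regulators also without KO day 3 replicate 3 (median -0.61, adjusted p = 0.054). OE day 0 replicate 2 aside, the medians without the arrays that these lists share were -0.38 to -0.3 for sarcomere, -0.4 to -0.27 for myogenic regulators and -0.63 to -0.49 for excitation coupling. Without Wt day 0 replicate 1, Wt day 3 replicate 2 or OE day 3 replicate 1 these calls were kept, at -1.21, -1.19 and -1.28 for sarcomere, -1, -0.98 and -0.98 for myogenic regulators and -1.57, -1.56 and -1.63 for excitation coupling. The sarcomere call was also kept without OE day 0 replicate 1 (-1) or 3 (-0.93). The interferon call was lost without Wt day 0 replicate 3 (-0.78), OE day 0 replicate 2 (-0.45) or OE day 3 replicate 2 (-0.77), and kept without Wt day 3 replicate 3 (-1.48). The glycolysis call was lost without any 1 of Wt day 0 replicates 2 and 3, OE day 0 replicates 1 and 3, Wt day 3 replicates 1 and 3, KO day 3 replicate 3 and OE day 3 replicate 3, at medians of -0.43 to -0.24. Median scaling ended the calls of myogenic regulators (-0.84), sarcomere (-0.82) and interferon genes (-0.93), which had adjusted p of 0.057, 0.061 and 0.1. No detection filter ended those of glycolysis (-0.36) and myogenic regulators (-0.61), the fit to the compared groups that of myogenic regulators (-0.61), and array weights that of interferon genes (-0.26). No gene was past the threshold in limma for either difference. An unadjusted p below 0.05 was found for 427 and 735 genes, where 596 are met by chance in each. With array weights the KO difference had 134 genes past the threshold.

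With no gene past the threshold, 0 genes were shared between the KO and OE responses at day 0 or day 3, and 0 between the days for either label. Across genes, which are not independent replicates, the KO and OE log2 differences had a correlation of 0.15 and a covariance of 0.017 at day 0. At day 3 these were -0.17 and -0.0235. The day 0 correlation was 0.55 without Wt replicate 1, 0.33 without Wt replicate 3, 0.06 without KO replicate 1 and 0.07 without OE replicate 2 of that day. The day 3 correlation changed sign without Wt replicates 1, 2 or 3 (0.03, 0.19 and 0.26) or OE replicates 2 or 3 of that day (0.13 and 0.04). It was -0.42 without OE replicate 1 and -0.09, -0.1 and -0.28 without KO replicates 1, 2 and 3. Both comparisons use the same Wt arrays, and 1000 simulated draws of unchanged groups gave a median correlation of 0.53, with 95% of draws between -0.46 and 0.93, and a median covariance of 0.0528. The observed values lay inside the simulated ranges. The draws used deviations of the arrays from their labelled group means, which hold the differences between arrays of unlike sets. The simulated range was therefore wide, and lying inside it decides nothing about a shared response. The 3 Wt arrays of a day cannot be split into parts of 2, so part of any correlation may come from the shared arrays. Between the days, the correlation of log2 differences was 0.07 for KO and -0.08 for OE. Leaving out 1 array gave -0.39 (KO day 0 replicate 1) to 0.38 (KO day 0 replicate 3) for KO and -0.41 (Wt day 0 replicate 1) to 0.36 (OE day 0 replicate 2) for OE, so neither had a stable sign.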

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

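The tests of the sets of arrays, of the probes without a gene name and of other splits were chosen after the resemblance between arrays, or the zero counts of genes, had been seen.

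The 6 sets of 3 mutually closest arrays cut across the labelled groups, and each held more than 1 label. Hybridisation or signal batches that shift the background predict a background that follows the sets, but 13.4% of the variance of background lay between sets, below the median of 27.5% over 10000 random sets of 3. Culture batches of 3 dishes, in which differentiation raised the sarcomere genes, predict a difference between days inside a set. With sets formed without the muscle and cell cycle genes, the largest such difference was 0.091 log2, beside a range of 2.11 over all arrays. However, sets join the arrays most alike over all other genes, and all 18 arrays kept their set without those 113 genes. A small difference inside a set was thus built in, and the test cannot decide about such batches. Labels that do not match the RNA on some arrays stay open, as do batches that leave the background unchanged and culture batches. Gata4 cannot check the labels, as it was at least 2 log2 above the lowest probe on 0 of 18 arrays. The position of its probe was not analysed either. Sarcomere means were 11.17, 11.23 and 11.32 in Wt replicate 1, KO replicate 1 and OE replicate 2 of day 0. They were 9.6, 9.27 and 9.48 in Wt replicate 2 and OE replicates 2 and 3 of day 3. Wrong labels, or cultures that did not follow the medium, would both give such levels, so these levels alone cannot decide. The 3 probes of the next paragraph were high on 2 of 6 Wt and 4 of 6 OE arrays, at high and at low sarcomere means. Cultures that did not follow the medium would not give that split. For the Wt and OE arrays, it argues against such cultures as the only account.

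Probes ILMN_1221149, ILMN_1245887 and ILMN_2473811 have no gene name here and were outside the gene tests. They drew attention because 6 arrays stood above the other 12 by at least 8.9, 8.8 and 8.48 log2, with the other 12 at 5.04 or below. A sequence delivered with the GATA4 virus would be high on all 6 arrays labelled OE if the labels held, but it was high on 4 of them, on 2 arrays labelled Wt and on 0 labelled KO. A sequence present in whole sets of mutually closest arrays leaves no set mixed, and 0 sets were mixed. The sets were formed without these probes, but this describes the pattern and names no cause. The sequence was thus shared by arrays of 2 sets, and what it is stays open. Sarcomere means were 11.17, 11.32 and 11.26 in 1 of these sets and 9.3, 9.35 and 9.27 in the other. Sets without it also held both levels, such as 11.36 in KO day 3 replicate 1 and 9.66 in KO day 0 replicate 2. The sets thus differed both in muscle level and in this sequence, and the labels followed neither. With labels as given, batches would have to bring the sequence to 2 Wt arrays and to only 4 of 6 OE arrays. Retroviral delivery remains a candidate source only if labels differ from the RNA on some arrays.

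Gene lists whose change over time differed between labels in the camera test of the difference were also followed up. For KO against Wt these were the interferon list (median log2 difference -2.74), p53 targets (-0.38), NF-kB genes (-0.6) and oxidative phosphorylation (0.22). For OE against Wt these were myogenic regulators (-0.61), sarcomere (-0.58), excitation coupling (-0.97), interferon (-0.87) and glycolysis and hypoxia (-0.43). None of the 9 was past the threshold with an estimated correlation, where the lowest adjusted p was 0.092. Leaving out 1 array kept the KO interferon and NF-kB calls, at medians of -3.85 to -1.81 and -0.81 to -0.32, while each of the other 7 calls was lost without at least 1 array. KO day 0 replicates 2 and 3 and Wt day 3 replicate 2, which form 1 set, had interferon means of 9.24, 9.24 and 9.23. Their NF-kB means were 7.36, 7.36 and 7.24. Other arrays had at most 6.94 and 7.06. Leaving out 1 array leaves the rest of that set in place, so it cannot test whether these calls rest on the set.

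The counts of genes past the threshold were set against other splits of the same arrays. The real count was 0 in each of the 9 comparisons, so that every split reaches it and the number that do says nothing about chance, for the 10 splits of each comparison of 3 arrays with 3, too few for a share under 0.05, as for the 100 splits drawn for each change over time. The highest count of another split was 2312 for day 3 against day 0 in Wt, 71 in OE and 0 in KO. It was 8 for KO against Wt at day 3 and 0 for KO against Wt at day 0 and for OE against Wt at either day. For the change over time it was 52 for KO and 3628 for OE. The split with 2312 genes put Wt day 0 replicate 1 with Wt day 3 replicates 1 and 3, against the other 3 Wt arrays, which points to a structure of the arrays that the labels do not follow.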

How the results depend on the processing

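One setting was chosen after seeing the data and leaves out, in each group, the array least correlated with its group (Wt day 0 replicate 1, KO day 0 replicate 1, OE day 0 replicate 2, Wt day 3 replicate 2, KO day 3 replicate 3, OE day 3 replicate 1). Its p-values are too small, since the arrays kept were chosen for their agreement.

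The count of genes past the threshold stayed at 0 in all 9 comparisons under the other normalisations, the authors' values, other filters, probe choices, a fit to the compared groups and a minimum log2 difference of 1. It was also 0 with the replicate block. Replicate numbers showed no pairing of the arrays. Of 45 same-number pairs, 18 had a correlation of deviations over 0.1, with a median of 0.01, and 7 of 18 arrays correlated best with their own number. Deviations from the group means hold the differences between arrays of unlike sets, so a weaker pairing could go unseen. Leaving out 1 array gave 0 to 10 genes for KO against Wt at day 0 and 0 elsewhere. Array weights favour arrays near their group, so their p-values may also be too small. They gave 1055 genes for KO and 961 for OE against Wt at day 0 (153 shared). The counts were 663 for day 3 against day 0 in Wt, 6266 in KO and 134 for the KO change over time. The added setting gave 514 for KO against Wt at day 0, 3675 for OE against Wt at day 3, 3927 for day 3 against day 0 in Wt, 4151 in KO, and 119 and 3014 for the KO and OE changes over time. The cause was not tested.

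All 45 list calls were lost with an estimated correlation, leaving 0 lists in each comparison. Under the other settings, leaving out single arrays aside, 42 of 540 list results lost their call. Array weights ended 10 calls, median scaling and no detection filter 4 each, the fit to the compared groups 3, cyclic loess 2, the other planned settings 1 each, and the added setting 13. A count of lists can hide such losses, since other lists came in. Kept calls were over 1.5 times smaller for 14 lists with no background correction, 14 with the authors' values and 8 with normexp by signal, and over 1.5 times larger for 16 with array weights and 19 with the added setting, which also made 4 and 2 smaller by as much. The remaining settings moved at most 4 kept calls each so far. For KO against Wt at day 0, 4 lists became 3 to 8 when 1 array was left out. For KO against Wt at day 3, 8 lists became 2 with array weights, 1 with the added setting and 1 to 10 without 1 array. For OE against Wt at day 0, 2 lists became 4 with normexp by signal, with the mean of probes or in the fit to the compared groups, 1 with cyclic loess, no detection filter or the replicate block, 7 with array weights or the added setting, and 1 to 12 without 1 array. For OE against Wt at day 3, 7 lists became 4 to 7 without 1 array. For day 3 against day 0, 5 lists in Wt became 8 with array weights, 9 with the added setting and 1 to 9 without 1 array, and 0 lists in OE became 1 with array weights or the added setting and 0 to 5 without 1 array. For the KO change over time, 4 lists became 7 with median scaling and 2 to 10 without 1 array. For the OE change, where median scaling ended 3 calls with the count still at 5, 5 lists became 8 with the authors' values, 3 with no detection filter, 10 with the added setting and 0 to 7 without 1 array.

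Medians changed sign for some calls. Without 1 array, KO against Wt at day 3 gave -0.06 to 0.62 for myogenic regulators, -0.05 to 0.9 for excitation coupling and -1.23 to 0.07 for cell cycle. The interferon list gave -0.12 to 1.4 for day 3 against day 0 in Wt, and the sarcomere list -1.28 to 0.07 for the OE change over time. With the added setting the cell cycle median was 0.12 for KO against Wt at day 3 and the interferon median 0.05 for the OE change over time. The cause was not tested. Gata4 stayed below the threshold throughout, with 8 changes of sign near 0. Of the 182 named gene differences, 72 were past the threshold with array weights and 113 with the added setting, and 5 signs changed. The slide as a block was not run, since slides were not used here. Median scaling shifted the median of all genes by 0.149 for KO and 0.157 for OE against Wt at day 0, -0.123 for day 3 against day 0 in OE and -0.168 for the OE change over time. The signal over background limits genes such as Gata4, whose values lay between 4.24 and 5.32 beside 4.13 for the lowest probe.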

Other observations

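Genes of the GATA family and of muscle identity, which the comparisons left below the threshold, varied between arrays. The values below were looked at after the resemblance of the arrays had been seen, and each is given array by array. Gata2, which encodes a zinc finger factor related to GATA4, was at 10.18 and 9.84 in KO day 0 replicates 2 and 3 and at 9.85 in Wt day 3 replicate 2, and lowest at 7.72 in OE day 0 replicate 2. Gata6 was near background, between 4.23 and 4.9, and detected on 5 of 18 arrays. Myod1, a regulator of muscle identity, lay between 10.1 and 11.15, and Myog between 9.63 and 11.58.

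Markers of other cell types and the remaining lists were measured on the same arrays. The mean of 8 macrophage and leukocyte markers lay between 4.87 and 5.57, and that of 9 endothelial markers between 4.85 and 5.49. Smooth muscle markers ranged from 6.2 to 7.63, with Acta2, which early muscle cells also express, between 12.88 and 14.53. Extracellular matrix genes ranged from 7.8 to 8.55 and fibroblast markers from 5.99 to 6.8. Cardiac genes ranged from 6.3 to 7.58, the GATA family and cofactors from 5.61 to 7.23, and endoderm and basement membrane genes from 5.93 to 6.4. Angiogenic factors ranged from 6.7 to 7.21, TGF-beta and BMP genes from 7.58 to 7.93 and Notch genes from 6.54 to 6.83. Of the lists too small to test, the mean of 4 adipocyte markers ranged from 6.44 to 7.08, of 3 glial markers from 5.29 to 6.11 and of 3 haemoglobin genes from 4.32 to 5.67. These are log2 intensities averaged over the measured members of each list.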
